A study of Mus musculus with 2 samples.

How the data were processed

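DNase-seq, in which the enzyme DNase I cuts DNA where it is not covered by nucleosomes and the cut ends are sequenced, was run on adrenal gland tissue of adult female mice of strain B6CASTF1/J, an F1 cross between C57BL/6J and CAST mice. The series held 1 group with 2 biological replicates, per the labels. The animals of replicate 1 were 9 to 13 months old and those of replicate 2 were 13 months old. Both replicates carry the same donor label, so how many animals stand behind each library is not given in the sources used here. With 1 group there was no contrast between conditions, and each library was measured by itself and set beside the other.

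The authors deposited, for each replicate separately, 2 peak lists that differ in stringency, a list of footprints, and a list of stretches of the genome with the false discovery rate of the local cut rate, all on build mm10 per the labels. The aligner, the peak caller and their versions are not given in the sources used here. The peak signal in the deposited lists is the authors' own scaled tag density per peak. Its values were whole multiples of 1 step per library within a tolerance of 0.05 of a step (99.9998% of the values of replicate 1 and 100% of those of replicate 2). The step was 0.00107 in replicate 1 and 0.00496 in replicate 2. If 1 step stands for 1 tag and both libraries were scaled to the same total, replicate 1 was sequenced 4.65 times as deeply. The scale of the signal is not stated in the sources used here, so the numbers of tags given in the text hold only if 1 step is 1 tag. They are the signal divided by the step, and need not count every tag across the width of a peak. The deposited false discovery rate files hold a p-value type of quantity, the authors' false discovery rate per stretch, and its highest value was below 0.05 in both replicates. The footprint files carry the constant 0.01 in the p-value column of every line, which is a threshold of the authors' call and no value per footprint. Every peak of the more stringent lists held a base with a false discovery rate of 0.001 or lower, against 63.2% of the peaks of the less stringent list in replicate 1 and 66.1% in replicate 2.

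The less stringent list was the main list. Peaks within 1 list can overlap each other (4.36% of the peaks of replicate 1 and 1.62% of those of replicate 2 overlapped an earlier one), and covered bases were counted after merging. A replicated region was made by merging the peaks of both replicates that overlapped by at least 1 bp, and it took the highest signal of its peaks in each replicate. Positions were compared with the GRCm38.p6 sequence and the GENCODE vM21 annotation, the same build as mm10, and 0 intervals lay past a chromosome end. A region was placed by its centre, in the order promoter (within 500 bp of the start of a protein-coding transcript), exon, intron and intergenic. A promoter counted as accessible where both replicates had a peak within 500 bp of any of the gene's protein-coding transcript starts, and the promoter signal of a gene is the highest peak there in each replicate, so the peaks behind the values of both replicates can lie at different starts. A distal region overlapped no promoter window and was assigned to the nearest protein-coding start within 50 kb.

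The 16 gene lists (212 genes, all found in the annotation), the 23 consensus sequences and the tests were fixed before the data were examined. The lists were steroidogenic cortex, zona glomerulosa, zona fasciculata and X-zone, chromaffin medulla, endothelium, capsule and stroma, macrophage and myeloid, T and B lymphocyte, Schwann and sustentacular glia, adipocyte, kidney, liver, skeletal muscle, erythroid, ovary and testis, and housekeeping. The share of a list's promoters that were accessible was compared with 10000 random lists of the same size matched on the decile of promoter CpG content, and the median number of distal regions with 10000 random lists matched on the decile of the length of genome nearest to each gene. These comparisons were two-sided permutation tests with Benjamini-Hochberg adjustment over the 16 lists, at an adjusted p of 0.05. Genes of a list are not independent replicates, so each p describes these 2 libraries. The log2 ratio of signal between the replicates was centred on the median over all replicated regions, and a list's median was given as a percentile of 10000 random sets of regions matched on signal, with no p. The share of distal regions with a consensus match in the 150 bp about the centre was divided by the share in windows 1000 bp to either side, and the share of matches with their centre in a footprint was taken per replicate. Both were set against up to 20 shuffled versions of the same sequence. Chance overlap of peaks came from 100 random placements of the peaks within their chromosomes outside assembly gaps, and that of footprints from 20 random placements within their own peaks. Intervals of shares are exact 95% Clopper-Pearson intervals and cover counting error only.

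The genes with values in the text were picked by a rule: per list, up to 5 members with the highest mean promoter signal and up to 4 with no promoter peak in either replicate, and over all protein-coding genes, the 15 with the most distal regions, the nearest genes of the 10 strongest distal regions, and the 5 promoters per direction with the largest ratio between the replicates among genes at or above the median signal. Genes named outside this rule are marked as such. Alternatives covered the more stringent list, reciprocal overlap of 50%, the strongest peaks of replicate 1 limited to the number in replicate 2, promoter windows of 250 and 1000 bp, no CpG matching, assignment within 100 kb or to every gene within 50 kb, other windows and flanks for the consensus sequences, whole matches inside footprints, centring on total signal, promoter or distal regions alone, autosomes and X only, and each replicate alone. Random gene lists in place of random regions were added after the data were seen. The list tests, interval overlaps and sequence searches were tested on simulated data first. In 10 simulations of 16 lists of 15 genes drawn from 21853 genes, the promoter test called 38 of 40 planted lists and 1 of 120 unplanted lists, and the distal test called 40 of 40 and 1 of 120. The planted differences were strong and all lists had 15 genes. These counts therefore do not show how often the tests would find smaller differences, or differences in shorter lists. All 9 checks of the interval and sequence functions gave the planted numbers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used, with bedtools 2.31.1 in the tests on simulated data.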

Results

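Accessible chromatin of the mouse adrenal gland, which makes steroid hormones in its cortex and catecholamines in its medulla, was mapped by DNase-seq in 2 biological replicates of adult females. Replicate 1 held 423866 peaks covering 104 Mb and replicate 2 held 173301 peaks covering 36.4 Mb, a ratio of 2.45 in number. The mean was 298584 peaks ± 177176 (SD, n = 2). The median peak was 220 bp wide in replicate 1 and 200 bp wide in replicate 2. If 1 step of the signal is 1 tag, the median peak signal stood for 189 tags in replicate 1 and 116 tags in replicate 2. The stretches with a false discovery rate below 0.05 covered 171 Mb in replicate 1 and 59.7 Mb in replicate 2. The more stringent lists held 262241 and 110676 peaks.

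The first comparison asked how far the 2 replicates found the same sites. Nearly every site of the smaller list was present in the larger one: 90.5% of the replicate 2 peaks (95% interval 90.3 to 90.6) overlapped a replicate 1 peak, where random placement gave 7.33%. In the other direction 36.2% of the replicate 1 peaks (36.1 to 36.4) overlapped a replicate 2 peak, where random placement gave 3.25%. The share depended on the strength of the site, and rose from 0.323% in the lowest decile of replicate 1 signal, at a median of 37 tags, to 98.9% in the highest decile, at a median of 1522.5 tags. With the strongest peaks of replicate 1 limited to the number in replicate 2, 76% of the replicate 2 peaks and 73.9% of the replicate 1 peaks overlapped.

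**Figure D1:**
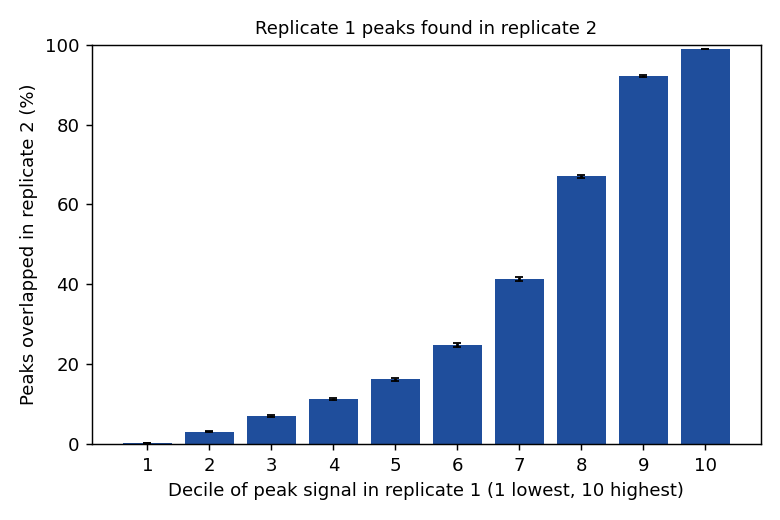
Share of replicate 1 peaks overlapped by a replicate 2 peak (y axis, percent) in each decile of replicate 1 peak signal (x axis); bars are shares over all peaks of the decile, with exact 95% binomial intervals. The share was 16.3% in the fifth decile, 41.3% in the seventh and 92.1% in the ninth.

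Merging the overlapping peaks gave 146522 replicated regions. Across these regions the log2 signals of the replicates had a Pearson r of 0.946 and a Spearman rho of 0.934. Over the 21427 regions that touched a promoter window r was 0.971, and over the 125095 distal regions it was 0.923. These correlations are across regions within 1 pair of libraries, and regions are not independent replicates.

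The second comparison placed the replicated regions in the genome. Promoters of protein-coding genes held 12.5% of the regions (95% interval 12.3 to 12.6), 8.85 times the share of randomly placed regions. Exons held 8.03% (1.74 times chance), introns 44.8% (1.05 times) and intergenic sequence 34.7% (0.676 times). Promoter regions were also the strongest, with a median signal of 2.13 in replicate 1 and 2.63 in replicate 2, against 0.491 and 0.601 in introns. Of the 1000 strongest regions 88.7% lay in promoters. The promoter share was 6.19% over the peaks of replicate 1 alone and 12.8% over those of replicate 2 alone.

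The third comparison asked which genes had an accessible promoter. Of 21853 protein-coding genes 14627 (66.9%) had a promoter peak in both replicates, 1491 had one in replicate 1 alone and 76 in replicate 2 alone. The share was 7.27% in the lowest decile of CpG content and 98.2% in the highest, which is why the lists were compared with genes of matched CpG content. Genes of steroid synthesis stood above their matched lists: 23 of the 24 promoters of the steroidogenic cortex list were accessible (95.8%) against a matched mean of 70.2% (adjusted p = 0.0008 by the permutation test, the smallest that the random lists can give here). The highest promoter signals of this list, given as replicate 1 and then replicate 2, were at Por, the reductase that feeds electrons to microsomal P450 enzymes (7.66 and 18.9), at Fdxr, which does so in mitochondria (7.09 and 14.8), and at Hmgcs1 (6.45 and 14.3), Msmo1 (4.32 and 10.5) and Stard4 (4.38 and 9.75), which act in cholesterol synthesis and transport. Hsd3b1, named after its values were seen as the 1 exception, had a promoter peak in replicate 1 alone, with a signal of 0.519.

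Star, whose protein carries cholesterol into mitochondria, is the first gene of the list and was taken for the map. It lies on the plus strand of chromosome 8 from 25806555 to 25815982 (mm10). Its promoter region ran from 25806161 to 25806600, upstream of and across the annotated start. The highest peaks within 500 bp of its transcript starts had a signal of 3.77 in replicate 1 and 7.37 in replicate 2, at different starts of the gene, and 14 distal regions were assigned to it.

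**Figure D2:**
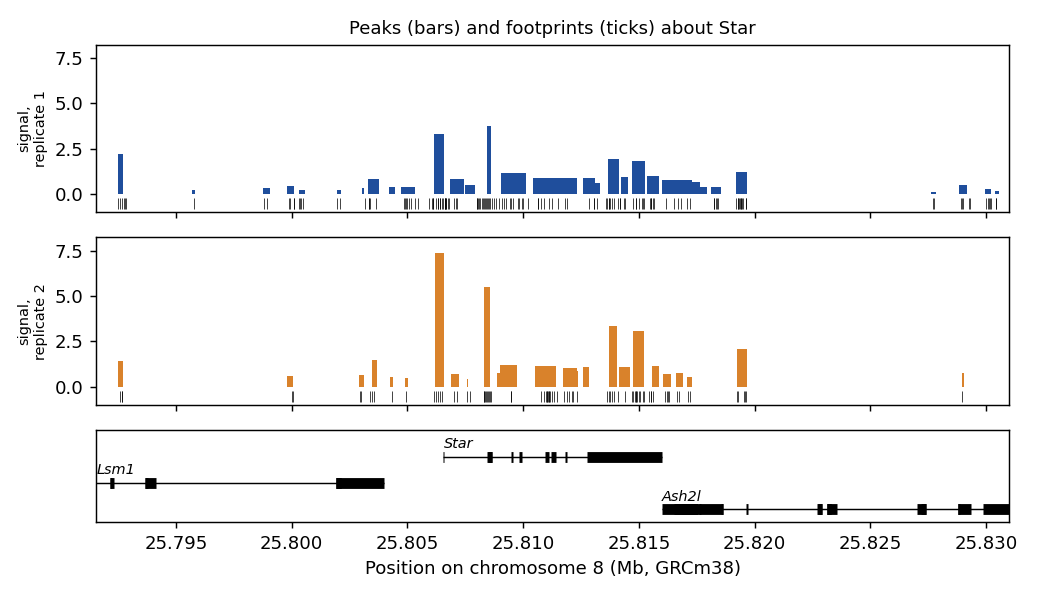
Peaks and footprints about Star on chromosome 8 (x axis, position in Mb), from 15 kb before to 15 kb after the gene; bars show each peak's position and signal in replicate 1 (top) and replicate 2 (middle), ticks show footprints, and the lowest panel shows protein-coding genes with exons as thick lines. The stretch held 36 peaks and 155 footprints in replicate 1 and 25 peaks and 85 footprints in replicate 2.

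Genes of the other cell types of the gland were accessible in number as well. In the chromaffin medulla list 23 of 24 promoters were accessible, against a matched mean of 83.6% (adjusted p = 0.131 by the permutation test, not past the threshold). Its highest signals were at Slc18a1, a transporter that loads catecholamines into vesicles (5.87 and 11.5), Chgb, a granule protein (2.995 and 4.49), Gata2 (2.08 and 3.01), Scg2 (1.89 and 2.82) and Isl1 (0.921 and 1.74). The Slc18a1 promoter has a start of Atp6v1b2 within 1 kb. Pnmt, which makes adrenaline and is named after its values were seen, had a promoter peak in replicate 1 alone (0.224). In the zona glomerulosa list 11 of 12 promoters were accessible (matched mean 74.8%, adjusted p = 0.131 by the permutation test), with the highest signals at Dab2 (3.41 and 4.66), at Agtr1a, an angiotensin II receptor (2.94 and 3.47), and at Nr4a2 (2.51 and 3.78). All 5 promoters of the zona fasciculata and X-zone list were accessible (matched mean 62.5%, adjusted p = 0.131 by the permutation test), from Abcb1b (2.03 and 3.22) and Akr1b7 (2.05 and 2.40) down to Akr1c18 (0.624 and 0.854), Pik3c2g (0.728 and 0.452) and Srd5a2 (0.441 and 0.417). With every promoter of this short list accessible, the permutation test gave an unadjusted p of 0.0578. In this setting it could therefore not have called the list above its matched lists.

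The endothelium, adipocyte, and macrophage and myeloid lists stood above their matched lists too. All 15 endothelial promoters were accessible (matched mean 63.8%), among them Esam (1.51 and 2.15), Flt1 (1.45 and 1.76) and Kdr (1.31 and 1.48). All 10 adipocyte promoters were accessible (matched mean 41.6%), led by Plin1 (1.57 and 2.52), Cidea (0.979 and 1.39) and Pparg (0.855 and 1.09). In the macrophage and myeloid list 10 of 14 were accessible (matched mean 22.4%), with low signals at Cd68 (0.781 and 1.07), Cd74 (0.753 and 0.864) and C1qa (0.318 and 0.491), and with no promoter peak in either replicate at Csf1r. Each of these 3 lists had an adjusted p of 0.0008 by the permutation test. With the more stringent peak list the adjusted p was 0.133 for endothelium, 0.0659 for adipocyte and 1 for macrophage and myeloid, and without CpG matching it was 0.0736 for adipocyte and 0.981 for macrophage and myeloid. The steroidogenic cortex list passed the threshold under all 6 alternatives, with a highest adjusted p of 0.0107. In the capsule and stroma list 12 of 15 were accessible (matched mean 54.9%, adjusted p = 0.0896 by the permutation test), with Pdgfra (2.26 and 2.55) and Gli1 (2.26 and 2.41) highest. It passed with the 250 bp window (0.0343) and in replicate 1 alone (0.0403).

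Of the remaining lists, which hold germ and gonad, liver, lymphocyte, blood, kidney, glial, muscle and housekeeping genes, 1 fell below its matched lists by the test. The ovary and testis list had 3 of 10 accessible promoters, Dazl (3.21 and 6.03), Sox9 (2.37 and 3.98) and Foxl2 (0.583 and 0.367), against a matched mean of 65.0% (adjusted p = 0.0102 by the permutation test). Zp3, Oosp1, Ddx4 and Prm1 had no promoter peak in either replicate. This call was lost with the 1000 bp window (0.1005), without CpG matching (0.0736) and in either replicate alone (0.118 and 0.155). The liver list had 2 of 12 (Foxa3 and Cyp2e1, matched mean 36.3%, adjusted p = 0.309 by the permutation test), with no promoter peak at Alb, Apoa1, Ttr or Serpina1a. The Foxa3 promoter has a start of Sympk within 1 kb. The T and B lymphocyte list had 3 of 12 (matched mean 45.9%, adjusted p = 0.145 by the permutation test), with no promoter peak at Cd3e, Cd3d, Cd4 or Cd8a. Its adjusted p was 0.0245 with the 250 bp window and 0.0178 without CpG matching. Without CpG matching the liver (0.0107) and erythroid (0.016) lists passed the permutation test too, below their random lists. The housekeeping (0.016) and chromaffin medulla (0.0107) lists then passed above theirs. With the more stringent peak list the kidney list passed (0.0427, below its matched lists). By the same permutation test the erythroid list had 2 of 10 (26.2%, adjusted p = 1), the kidney list 5 of 12 (55.2%, 0.476), the glial list 5 of 10 (52.9%, 1) and the skeletal muscle list 7 of 12 (42.9%, 0.476). The housekeeping list had 15 of 15, close to its matched mean of 95.6% (adjusted p = 1 by the permutation test). With every promoter accessible, the test could not have called this list above its matched lists.

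**Figure D3:**
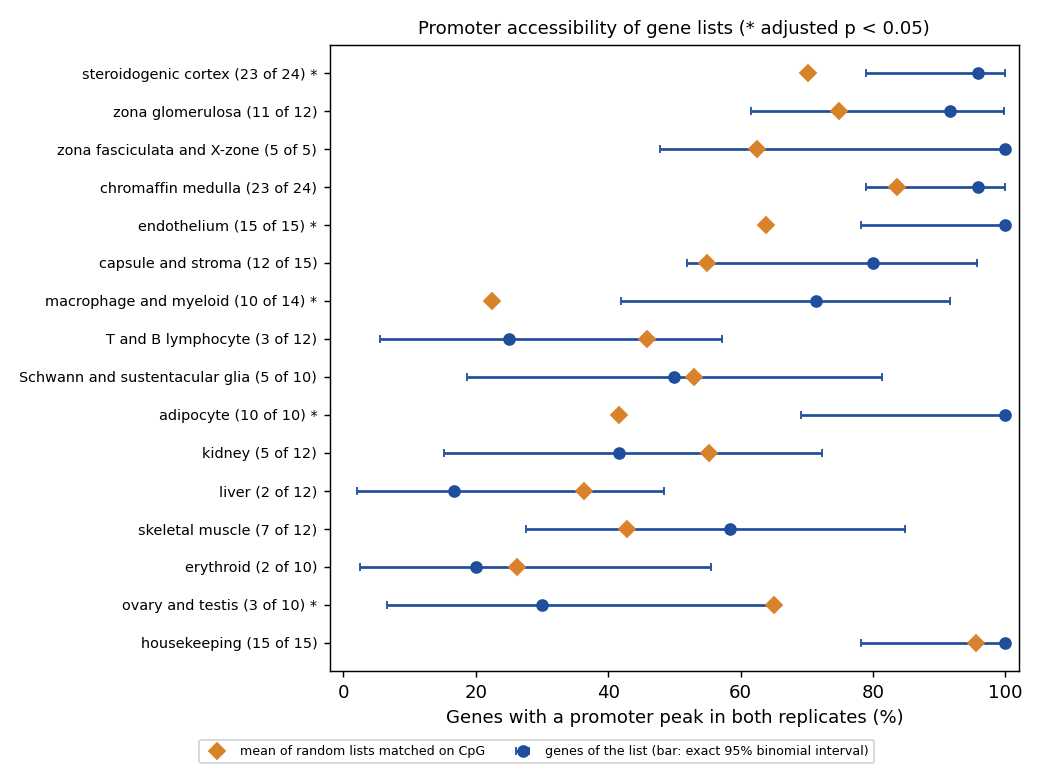
Share of each list's genes with a promoter peak in both replicates (x axis, percent), with exact 95% binomial intervals (circles and bars), beside the mean of 10000 random lists matched on CpG content (diamonds). Counts stand beside the names, and an asterisk marks an adjusted p under 0.05. The steroidogenic cortex, endothelium, macrophage and myeloid, and adipocyte lists lie above their matched means and the ovary and testis list below.

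The fourth comparison counted distal regions per gene. Of the 125095 distal regions 80629 (64.5%) lay within 50 kb of a protein-coding start. Genes of the steroidogenic cortex list had a median of 9 distal regions, where matched lists had a mean of 2.81 (adjusted p = 0.0032 by the permutation test), and 248 regions in all. The median was 31.5 in replicate 1 alone (matched mean 8.45) and 11 in replicate 2 alone (3.31), 5.5 with the more stringent list (1.68) and 15.5 with every gene within 50 kb (6.82). The gene of this list with the most was Cyp11a1, which encodes the side-chain cleavage enzyme that starts steroid synthesis, with 26. It was named after the counts were seen, as were Scarb1, the receptor for cholesterol-rich lipoprotein (21), and Nr5a1, which encodes the regulator SF-1 (17). The housekeeping list also stood above its matched lists, with a median of 5 against 1.33 (adjusted p = 0.0064 by the permutation test). Its median was 15 in replicate 1 alone (matched mean 4.55) and 3 with the more stringent list (0.756). With every gene within 50 kb it was 11 (6.44), and the list did not pass (0.127). By this permutation test none of the other 14 lists passed, among them adipocyte (5.5 against 2.22, adjusted p = 0.0747), zona fasciculata and X-zone (12 against 5.09, 0.146), endothelium (6 against 2.97, 0.146), zona glomerulosa (8 against 4.76, 0.25) and chromaffin medulla (4 against 3.62, 1). In replicate 2 alone the zona glomerulosa and adipocyte lists each had an adjusted p of 0.0456, and in replicate 1 alone zona glomerulosa had 0.0171.

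Over all genes the median was 2 distal regions and 5523 genes had none. Among the genes with the most were Tns1 (62), Zbtb20 (46), and Auts2, Gse1, Mtss1 and Psd3 with 43 each. Foxp1 and Pde4d had 42, B4galt5, Sept9 and Zfp423 had 41, Itpr1 and Tbx3 had 40 and Iqsec1 had 39. Tbx3, a T-box transcription factor gene, reached its number within 100.3 kb of nearest sequence, where Pde4d had 837 kb. Of the 10 strongest distal regions, those with Esp38, Limd1, Gm8797, Igf2bp3, Txndc11, Kpna1, Il31ra or Gm15319 as the nearest gene consisted mostly of 36-base words with other copies in the genome. Of 300 random distal regions 1.33% did. The starts of Esp38, Gm8797 and Gm15319 lay 104, 110 and 61.6 kb from their regions, beyond the 50 kb used for assignment. The remaining regions were at chromosome 15 from 99735641 to 99736060, an exon 10.2 kb from the start of Cox14 (signal 27.3 and 26.5), and at chromosome 11 from 98773761 to 98774180, an intron 1.36 kb from the start of Nr1d1, a gene of the circadian clock (10.3 and 23.2).

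The fifth comparison searched the distal regions for the binding sequences of known factors. The sequence of CTCF, a factor that organises chromatin loops, was in 4.38% of the distal regions, 32.8 times its share in the flanks, where the highest of 20 shuffled sequences reached 5.52 times. The AP-1 sequence was in 12.1% (4.48 times, highest shuffle 1.497), that of NR5A1 (SF-1), the main regulator of steroid-making cells, in 6.64% (3.66 times, highest shuffle 2.65), and that of CREB/ATF, which responds to cyclic AMP, in 0.377% (3.29 times, highest shuffle 1.93). The REST sequence was in 166 regions, 83 times the flanks, but only 6 of its shuffled versions could be scored. In the peaks of replicate 1 alone the ratios were lower, at 12.7 for CTCF, 2.63 for AP-1, 1.89 for CREB/ATF, 1.73 for NR4A and 31.7 for REST. With the 100 bp window CTCF reached 49.8, and with flanks at 2000 bp REST reached 55.3. The glucocorticoid receptor sequence reached 2.28 times (highest shuffle 2.21), but lay below its highest shuffle with the 100 bp window (2.22 against 2.24) and in replicate 2 alone (2.18 against 2.40). TCF/LEF reached 1.47 (1.19) and PU.1 1.39 (1.24). The NR4A sequence reached 2.61 times and ETS 1.75, both below their highest shuffles (3.06 and 2.58). GATA matches were no more frequent in the regions than in the flanks (0.975 times), though its shuffled versions stood lower still (highest 0.848). MEF2 reached 1.36 times (highest shuffle 0.647).

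**Figure D4:**
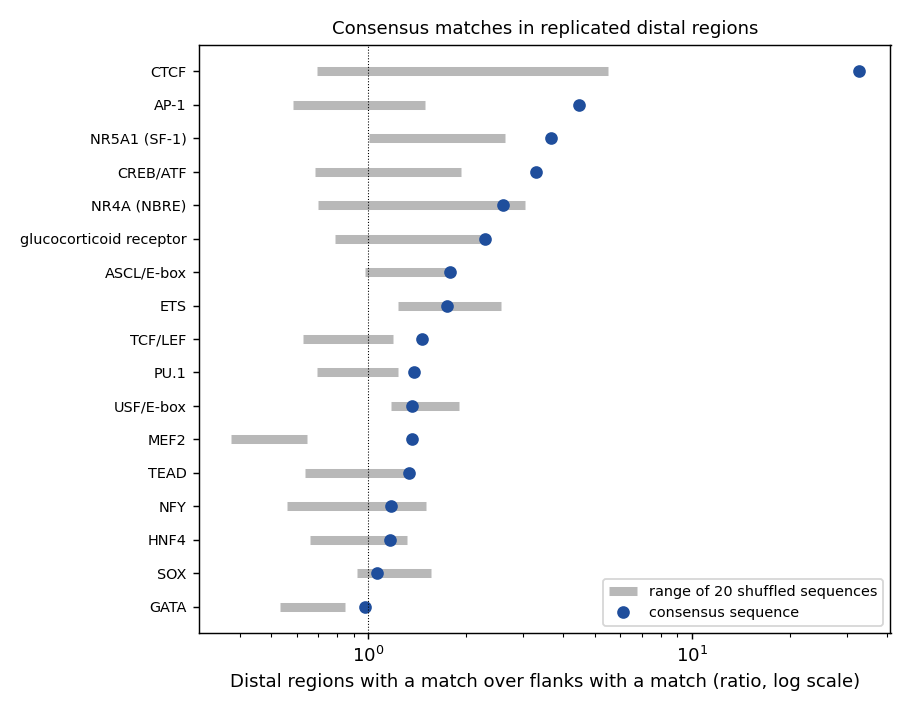
Ratio of the share of distal regions with a consensus match to the share of flanking windows with one (x axis, log scale), for the consensus sequences with at least 50 matching regions and 20 shuffled versions; circles are the consensus sequences and grey lines the range of their shuffles. CTCF stands at 32.8 (12.7 in replicate 1 alone), AP-1 at 4.48 (2.63) and NR5A1 (SF-1) at 3.66 (2.495).

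Footprints, short protected stretches inside accessible sites, numbered 1311402 in replicate 1 and 457374 in replicate 2, with a median width of 9 bp in both. Of these 79.8% and 86.4% lay in peaks of the same replicate. Of the replicate 2 footprints 60.6% overlapped a replicate 1 footprint, and of the replicate 1 footprints 20.4% overlapped a replicate 2 footprint. For replicate 2 footprints inside peaks the share was 60.2%, and 39.9% when they were moved at random within their peaks. CTCF matches in peaks lay under a footprint in 92.0% of cases in replicate 1 and 86.8% in replicate 2, against 20.9% and 20.5% for shuffled sequences. The share for REST was 93.5% and 73.1%, that for NRF1 87.4% and 95.8%, and that for CREB/ATF 60.4% and 72.5%. NR5A1 (SF-1) matches lay under a footprint in 45.2% and 45.0% of cases (shuffled mean 12.8% and 14.3%, highest shuffle 29.4% and 31.7%). AP-1 matches did so in 21.3% and 27.7% (shuffled mean 9.34% and 11.3%, highest shuffle 19.7% and 22.4%). The shares for GATA (5.03% and 6.75%), PU.1 (6.21% and 6.93%) and the glucocorticoid receptor (8.18% and 8.88%) were below the means of their shuffles. They lay inside the range of those shuffles in both replicates.

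The last comparison set the signal of the replicates side by side for each list, with 1 library on each side and so with no replicate check. Before centring, the median log2 ratio over all replicated regions was -0.362, toward replicate 2, and the centred ratios are relative to it. Relative to that median the capsule and stroma regions were stronger in replicate 1, with a centred median log2 ratio of 0.39 over 112 regions. This lay at the 100th percentile of random gene lists. The uncentred median signals of these regions were 0.540 in replicate 1 and 0.504 in replicate 2. Without Nr2f2, a nuclear receptor gene with 35 of these regions, the ratio was 0.18, and 8 of the 15 genes had a median above 0. Endothelial regions were stronger in replicate 2, with -0.16 over 135 regions (percentile 0.13) and 13 of 15 genes below 0. Erythroid regions stood at 0.30 over 29 regions (97.9), with an interval over genes from -0.10 to 0.43. The steroidogenic cortex list stood at -0.08, at percentile 2.31 of random regions but at 20.8 of random gene lists. The chromaffin medulla list stood at -0.02. Among the stronger promoters the largest ratios toward replicate 1 were at Dok4 (1.27), Med10 (1.09), Mettl26 (0.86), Usp45 (0.82) and Cpsf2 (0.79). The largest toward replicate 2 were at Camsap1 (-1.28), at the shared promoter of Usp20 and BC005624 (-1.27), and at that of Fancb and Mospd2 (-1.23).

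**Figure D5:**
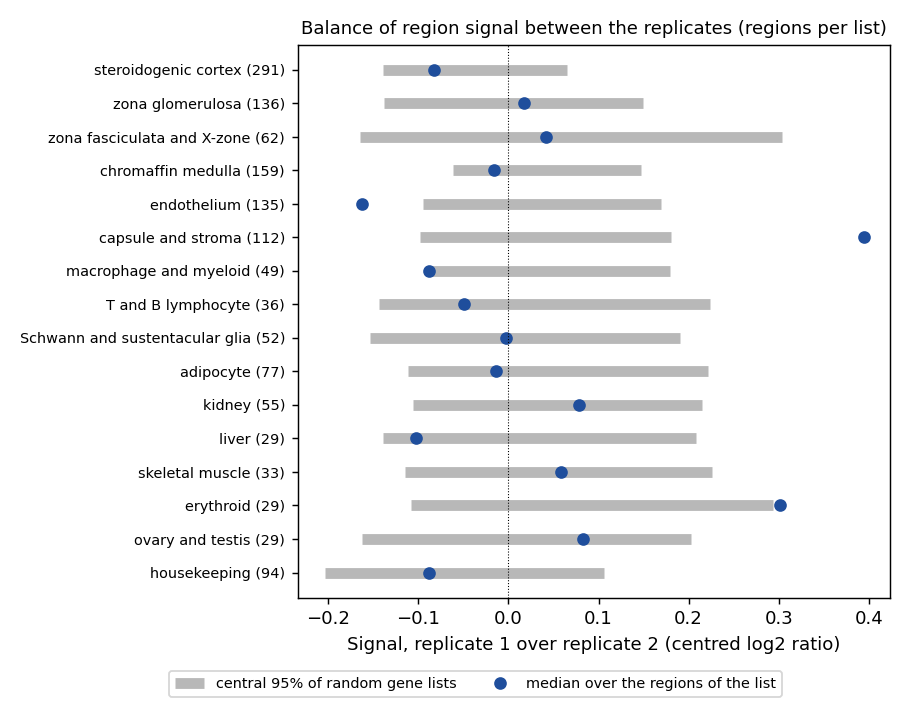
Centred median log2 ratio of region signal, replicate 1 over replicate 2 (x axis), for the regions of each list (circles), with the central 95% of random gene lists matched on signal (grey lines); the number of regions stands beside each name. Capsule and stroma lies above its range at 0.39, endothelium below at -0.16, and erythroid at 0.30 just above its range.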

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

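The tests of this part were chosen after both patterns were seen, and how the cell type test is judged was set after related values were seen. Peaks were called on chromosome Y, which female animals do not carry and which the report counted among all peaks but did not describe, 278 in replicate 1 (median signal 0.00907, all peaks 0.202) and 67 in replicate 2 (0.194, all peaks 0.576). DNA from male animals would open the promoters of Ddx3y, Kdm5d, Uty and Eif2s3y, single-copy genes of chromosome Y that are active in most male cells, and 0 of these 4 promoters had a peak in either replicate. Sequence shared with other places in the genome could account for most of the peaks: a median of 88.9% of the 36-base words of a chromosome Y peak in replicate 1 occurred elsewhere, against 0% in a sample of chromosome X peaks. Of 262 scored peaks 211 consisted mostly of such words, and the others, among them a run of wide peaks near the end of chromosome Y, stay open. No biological explanation was tested.

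Replicate 1 held 2.45 times as many peaks as replicate 2. Lower sequencing depth of replicate 2 could account for much of this. Of the 270343 peaks called in replicate 1 alone, 0.781% (2111) were expected to reach more tags in replicate 2 than its median peak of 116 tags. The expectation holds only if 1 step is 1 tag and both libraries were scaled to the same total. It also took the scaled signal as equal in both, where the median log2 ratio over replicated regions was -0.362, toward replicate 2. Of the peaks called in replicate 1 alone, 62.3% were expected below 35 tags, the 5th percentile of replicate 2 peaks. Depth therefore need not be the whole account of the others. Cell types with fewer nuclei in replicate 2 cannot be told apart from this, since steroidogenic cortex was lowest, at percentile 0.23 of matched random gene lists for the share of its replicate 1 peaks found in replicate 2 (33.1% against a matched mean of 45.0%), but the housekeeping list, which marks no cell type, stood at 0.56. The steroidogenic cortex regions found in both replicates had a centred median log2 ratio of -0.08, toward replicate 2. Its interval over genes, -0.17 to 0.03, spans both directions. It therefore does not settle whether replicate 2 held fewer cortical nuclei. The age of the animals, which differed in range between the replicates, was not tested.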

How the results depend on the processing

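Of 531 values recomputed under an alternative, 428 kept their call, moved by less than their spread or, for counts, stayed within a set fold. The threshold was lost by 25 values and gained by 17, and 39 moved further. Another 22 changed sign, whether or not they had passed a threshold in the main setting. The cause was not tested except where the alternative itself removes peaks. The more stringent list gave 262241 and 110676 peaks, shared 93.9% (replicate 2) and 39.0% (replicate 1), r = 0.938, and 58.2% and 68.6% of footprints inside peaks. It left 1 promoter list above and 2 below, with differences from matched lists of -2.19 percentage points for capsule and stroma and -2.73 for skeletal muscle. Its distal differences were 0.0906 regions per gene for T and B lymphocyte, 0.337 for glia and -0.0112 for skeletal muscle. Reciprocal overlap of 50% gave 63.1% and 25.8% shared peaks, r = 0.944, and shared footprints of 39.3% (replicate 2) and 13.7% (replicate 1). Equal numbers of peaks gave 76.0% and 73.9%. Distal regions alone gave r = 0.923. The number of promoter lists below was 0 with 1000 bp, 2 with 250 bp and 3 without CpG matching, where skeletal muscle stood at -8.55. With every gene within 50 kb, 1 distal list stood above, and the distal differences were -0.879 for chromaffin medulla, 1.63 for T and B lymphocyte and -0.235 for liver. Centring on total signal shifts every region alike, which by construction took steroidogenic cortex to 0.0365 and 8 of 16 lists to the other sign. Promoter regions alone changed the sign of 4 lists, distal alone 3 and the more stringent list 5. NRF1 stood at 0.40 (log2 over shuffles) with flanks at 2000 bp and SOX at -0.13 with whole matches in footprints. HNF1 under footprints had no finite value and was left out.

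With each replicate left out in turn, the lowest and highest values were 173301 to 423866 peaks, 457374 to 1311400 (rounded) footprints, 6.19% to 12.8% in promoters, 0 to 0 promoter lists below, and 3 to 4 distal lists above. For glia the promoter difference was -3.41 to 7.62 percentage points. The distal differences were -3.04 to -0.285 for kidney, -1.45 to 0.699 for liver, -1.48 to -0.0596 for skeletal muscle, -2.49 to -0.0960 for erythroid and -2.34 to 0.0519 for ovary and testis. USF/E-box in footprints stood at -0.25 to 0.33. No paired analysis was possible because the series has 1 group. Random gene lists in place of random regions were chosen after seeing the data. They took steroidogenic cortex inside the central 95%. Regions weak in replicate 1 were seldom found in replicate 2.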

Other observations

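Chosen only after the result was seen were the ratios of the consensus sequences between the replicates with their matching, the second lists, the matching on GC content, the copies of sequence, the search for NR5A1 (SF-1) matches by list, and the bounds used to judge the CTCF excess and the weight of 1 gene. NR5A1 (SF-1) matches were about as frequent near the genes of steroid synthesis as in distal regions as a whole. Of the 248 distal regions of the steroidogenic cortex list 16 (6.45%, 95% interval 3.73 to 10.3) held a match, against 6.64% of all distal regions and 1.82% of their flanks. In the promoters of this list 3 genes held a match, Cyp11a1 (TCAAGGTCA on chromosome 9 from 58006206 to 58006214), Lipe, a hormone-sensitive lipase, and Scarb1, and 0 of these matches lay in a footprint in either replicate. In promoters of the housekeeping list 4 of 15 genes held a match, in chromaffin medulla 2 of 24 and in endothelium 1 of 15. Of the matches in these lists 1, in the housekeeping list, lay in a footprint, in replicate 1 alone. The share of distal regions by list was looked at for 6 consensus sequences in 16 lists, without a test.

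Distal regions with a CTCF match were stronger in replicate 1, with a centred median log2 ratio of 0.53 over 5478 regions, the second largest of the 20 consensus sequences compared, after REST (0.54 over 166 regions). AP-1 (-0.17), NR5A1 (SF-1) (-0.14) and CREB/ATF (-0.28) regions lay the other way. The excess over random distal regions matched on signal was 0.61. It stayed at 0.60 with GC content matched as well and at 0.61 among regions whose sequence has no other copy, so neither accounts for it. Matching on width brought it to 0.33, so part of the excess went with width and part did not. Whether width was a cause was not tested. No biological explanation was tested.

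As own hypotheses on the cell make-up of the replicates, the capsule and stroma list and the endothelium list were followed up after both were seen to lie outside random gene lists. The erythroid list also lay outside and was not followed up. Whether replicate 1 held a larger share of stromal nuclei stays open. A second stromal list stood at -0.05, at percentile 6.06 of random gene lists and inside their central 95%, but its genes went both ways, with 10 of 27 above 0, among them Postn (0.80) and Tbx18 (0.62), and Meox1 at -0.36, named after their values were seen. That the spread over these genes leaves the test open was settled after their values were seen. GC content did not account for the first list, which stayed at percentile 99.99 with GC matched. Whether the pattern rests on 1 gene cannot be told apart. Without Nr2f2 the ratio was 0.18, at the upper bound of random lists as long as the whole list (0.178). The interval over genes was -0.01 to 0.56. The endothelial list stayed at percentile 0.31 with GC matched, which argues against GC content there. It stood at -0.15 without its most influential gene, and stayed below the lower random bound of -0.10 with any gene left out (-0.21 to -0.15), so 1 gene does not carry it. How far the medians vary as genes are left out was chosen as the yardstick for this after their values were seen. A second endothelial list stood at -0.08 (percentile 4.43), with 9 genes above 0 and 10 below, between the bounds set before this list was computed, so more endothelial nuclei in replicate 2 stay open as a possible explanation.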
